A study of Homo sapiens with 17 samples.

How the data were processed

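RNA-seq was measured in C4-2B cells (written C42B in the labels), a human prostate cancer cell line that expresses the androgen receptor. The 17 libraries comprise 1 untreated library at day 0 and 2 libraries each of DMSO (the solvent control) and of enzalutamide (an antagonist of the androgen receptor) at days 7, 28, 49 and 91. Groups, days and replicate numbers were taken from the labels. The design text of the series gives 1 replicate for each treatment and day, whereas the labels number 2 libraries, and neither says whether these came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels also do not say whether different days were sampled from the same cultures, so the days may not be independent.

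The deposited table holds estimated counts per gene symbol, which the authors made by scaling TPM values by transcript length, per the file name, which also gives GENCODE release 28. The reads were quantified with kallisto on hg38, per the submitters' processing notes, and the version is not given in the sources used here. Estimated counts need not be whole, and kallisto divides a read that matches several transcripts among them, so values of near-identical genes (the HLA genes, UGT2B15 and UGT2B17, KLK2 and KLK3, PRSS1) are uncertain. Whether the counting used strand is not given in the sources used here. The table has 56795 rows. Symbols were paired with GENCODE release 29 on GRCh38 for coordinates and gene types: 51.9% of rows matched by symbol and 1.7% through another symbol, 0.3% matched several genes, and 46.1% did not match. Coordinates below are from that release. No transcript encoded by the mitochondrial genome has a row in the table used here, so that list was not measured.

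Library totals ranged from 27129932 to 36862260 estimated counts, so that 3 counts, the limit a count of 0 allows, corresponded to 0.0846 to 0.111 CPM per library. Such limits cover counting error only. Replicates of a group correlated at r = 0.976 to 0.981 across genes on log2 CPM, and their counts differed by more than sampling noise in every group (chi-square per gene 9.68 to 46.4), so no library was counted as a duplicate.

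Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr over the 8 groups (minimum count 10, minimum total 15), which left 23137 genes. Libraries were scaled by TMM over all 17 libraries. A model with 1 mean per group of treatment and day was fitted to the 16 treated libraries (8 residual degrees of freedom) with edgeR 4.0.16 in R 4.3.3, and contrasts were tested with its quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes with an adjusted p under 0.05 were called. Log2 fold changes are given with standard errors derived from the test, as the absolute log2 fold change divided by the square root of F. They therefore hold the same information as the p-value and are approximate at low counts. The main contrast was the mean over the 4 days of the difference between enzalutamide and DMSO of the same day. Single days, day 91 against day 7 in each treatment, the difference of the enzalutamide effect between days 91 and 7, and a 3-degree-of-freedom test of any difference among the 4 days were also tested. The day 0 library has no replicate and entered no test.

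Gene lists were fixed before the data were examined (20 lists) and tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists are over all lists measured. Camera compares a list with the other genes, whereas fry tests the list alone. Named genes follow a rule fixed before the data were examined. It takes 17 genes of the androgen receptor and MHC class I pathways, the 12 rising and 12 falling protein-coding genes with the largest mean change that kept their sign on 4 days (adjusted p under 0.05, mean log2 CPM of at least 1), the 5 and 5 largest for each day and for enzalutamide over time, the 10 and 10 largest for DMSO over time and for the difference between days 91 and 7 (in all of these protein-coding, with the same p and CPM limits and no overlap between the libraries compared), and up to 4 called members of each list, or the 2 of highest expression where none was called. The text gives the values of part of these genes, and some of them are not reported here.

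The alternatives were DESeq2's size factors, DESeq2 1.42.0, limma voom on unrounded values, no filter, a mean CPM of at least 5, a replicate block, leaving out each of the 16 libraries, a log2 fold change of at least 1, an adjusted p under 0.01, only the groups compared, and an additive model. For DESeq2, lists were tested with cameraPR on its Wald statistics. A cell cycle score (the mean log2 CPM of the cell cycle list) as a covariate, the same covariate with an estimated correlation for the lists, the mean without day 28, and other settings for the correlations between days and for the named genes of single days and time contrasts were added after seeing the data, as were contrasts of the enzalutamide effect between days 91 and 28 and between days 28 and 7. The cell cycle scores of the treatments did not overlap, so this covariate cannot separate cell division from treatment. When a library was left out, the genes tested were held as in the full set. This was decided after a first run had filtered again with 1 library in a group, which admitted more low-count genes and lowered the correlations between days whichever library was left out.

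The steps were tested on simulated counts with 200 changed genes, all drawn from genes with a mean CPM of at least 1. Counts were drawn with the spread that the same model estimated from these data. Recovery of genes below that level was not tested. For the mean of 4 days (22352 genes tested), 58% of genes changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 11 of 188 calls were false. For day 7 alone (22382 genes), 8% of genes changed 1.5-fold, 52% of those changed 2-fold and 88% of those changed 4-fold were recovered. For the difference between days 91 and 7 (22359 genes), 24% of genes changed 2-fold and 80% of those changed 4-fold were recovered, and 8 of 105 calls were false. In the list test the raised list was called, and 0 of 20 unchanged lists were. Simulated genes varied independently, so this does not cover lists whose genes vary together, such as the cell cycle list (estimated correlation 0.815). Far more genes were called in the data (10062) than were changed in the simulation. Figures were drawn with matplotlib in Python.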

Results

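Gene expression was measured by RNA-seq in C4-2B prostate cancer cells kept for 3 months in enzalutamide or in DMSO. Each treatment had 2 libraries at days 7, 28, 49 and 91, and 1 untreated library was taken at day 0. Library totals lay between 27129932 and 36862260 estimated counts. In a principal component analysis the first component held 38.1% of the variance. It placed all 8 DMSO libraries between -65.8 and -41.8 and all 8 enzalutamide libraries between 34.7 and 95.9. The day 0 library, which was projected onto this component and did not shape it, lay between the treatments at -1.1.

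**Figure D1:**
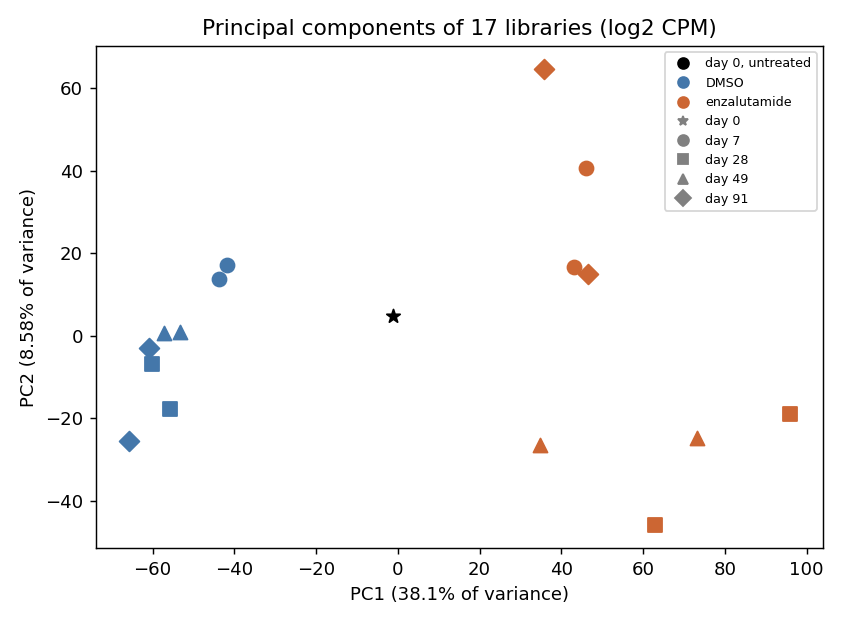
Principal components 1 and 2 of log2 CPM, with 1 point per library, coloured by treatment and shaped by day. DMSO libraries lie between -65.8 and -41.8 on the first axis, enzalutamide libraries between 34.7 and 95.9, and the day 0 library at -1.1. The axes were fitted without the day 0 library, which was projected onto them.

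The first comparison asked how blocking the androgen receptor changed expression relative to DMSO of the same day. Androgen receptor target genes fell. KLK3, which encodes prostate-specific antigen, averaged 3280 ± 610 CPM in DMSO and 478 ± 254 in enzalutamide (SD over 8 libraries each), a log2 fold change of -2.96 ± 0.17 (SE, adjusted p = 5.7e-09). Its neighbour KLK2 (-2.78 ± 0.18, adjusted p = 2.07e-08), the protease gene TMPRSS2 (-2.03 ± 0.12, adjusted p = 5.51e-09) and the co-chaperone gene FKBP5 (-1.52 ± 0.15, adjusted p = 1.61e-06) were lower as well. For all of these genes all 8 enzalutamide libraries lay below all DMSO libraries. KLK3 lies on chromosome 19 from 50854915 to 50860764 and KLK2 on the same chromosome from 50861568 to 50880567, both on the plus strand.

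Of the 30 genes in the list of androgen receptor activated genes, 25 fell, 1 rose and 4 were not called, and 26 fell when adjusted over the list alone. With the cell cycle score of each library as a covariate 20 were called lower. The list median was -1.52, and camera placed the list below the other genes (adjusted p = 4.44e-18, and adjusted p = 0.0485 with an estimated correlation). Strong declines included SLC45A3 (-3.71 ± 0.13), the transporter gene ABCC4 (-1.83 ± 0.09) and the methyltransferase gene NNMT (-5.17 ± 0.26). Of the 10 genes that the receptor is known to repress, 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (median 1.24, camera adjusted p = 0.000285, and adjusted p = 0.0485 with an estimated correlation). The androgen-glucuronidating enzymes UGT2B15 (6.13 ± 0.21) and UGT2B17 (5.49 ± 0.21) led these, with the reservation that such similar genes share reads. BCHE rose by 3.26 ± 0.22, whereas IGF1 was the member that fell (-2.95 ± 0.23).

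**Figure D2:**
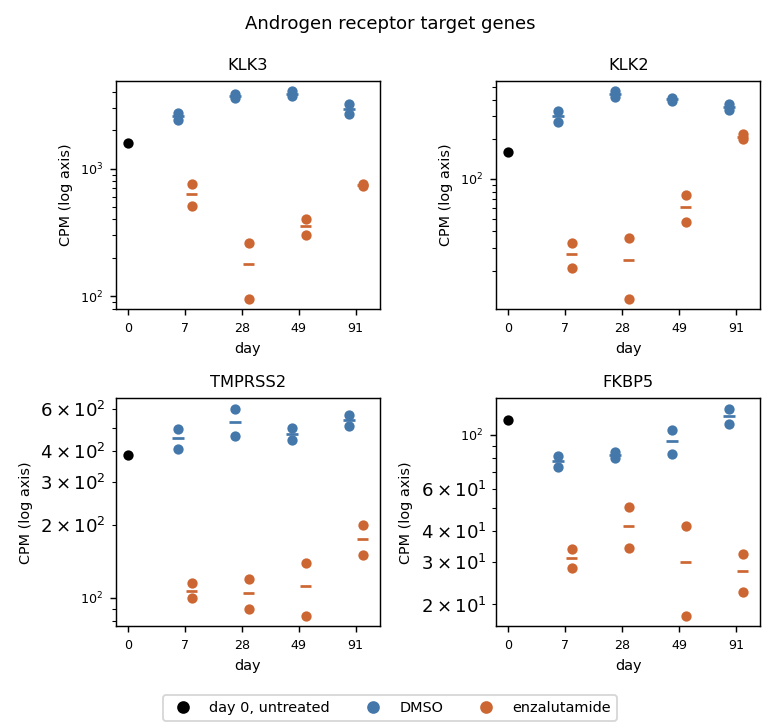
CPM on a log axis against day for 4 target genes of the androgen receptor, with 1 point per library and a bar at each mean of 2 libraries. KLK2 in enzalutamide approaches the DMSO level at day 91, with a log2 difference of -0.75, whereas TMPRSS2 stays at -1.62.

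The study asked about MHC class I, the complex that presents peptides to cytotoxic T cells. Of 21 measured genes of MHC class I antigen presentation, 16 rose, 1 fell and 4 were not called, with the same 16 and 1 when adjusted over the list alone. The median log2 fold change was 0.54, and camera placed the list above the other genes (adjusted p = 2.09e-06, and adjusted p = 0.0485 with an estimated correlation). HLA-C went from 106 ± 18.8 to 177 ± 38.6 CPM (0.73 ± 0.08, adjusted p = 3.8e-06), and 7 of the 8 enzalutamide libraries lay above all DMSO libraries. HLA-B (0.70 ± 0.09), HLA-E (0.44 ± 0.06) and the light chain gene B2M (0.46 ± 0.12, adjusted p = 0.00745) rose too. These HLA genes share reads with one another, so the division among them is uncertain. The peptide transporter gene TAP1 rose by 0.93 ± 0.10, TAPBP by 0.84 ± 0.09 and the proteasome activator gene PSME1 by 1.22 ± 0.09. TAP2 (0.28 ± 0.09, adjusted p = 0.0229) was no longer called without day 28 (adjusted p = 0.25), in an additive model (0.0542), or without 1 of 6 libraries: DMSO day 7 replicate 1 (0.0629), DMSO day 28 replicate 2 (0.0567), DMSO day 49 replicate 2 (0.0549), enzalutamide day 7 replicate 1 (0.071), day 28 replicate 1 (0.0678) or day 91 replicate 1 (0.0527). The immunoproteasome subunits rose from very low levels. PSMB9 went from 0.269 ± 0.198 to 2.87 ± 1.59 CPM (3.31 ± 0.36) and PSMB8 from 0.209 ± 0.0705 to 1.37 ± 1.02 CPM (2.47 ± 0.31). PSMB9 overlaps TAP1 and PSMB8 on the opposite strand, so any reads from sequence that their transcripts share cannot be told apart if the counting ignored strand. CANX, which encodes the chaperone calnexin, was the member that fell (-0.34 ± 0.10). NLRC5, a transcriptional activator of this pathway, had a log2 fold change of -0.07 ± 0.18 (adjusted p = 0.785). With the cell cycle score as a covariate the list median was 0.48 and camera called the list (adjusted p = 0.000275, and adjusted p = 0.0761 with an estimated correlation), but 1 of 21 members was called. Of the 17 members called without the covariate 8 moved nearer to 0, among them TAPBP (0.36), PSME1 (0.80), PSMB8 (1.33) and TAP2 (-0.18), and the median standard error went from 0.10 to 0.27.

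The list was above the other genes on each day by camera, with adjusted p = 2.32e-06 at day 7, 3.17e-07 at day 28, 3.39e-06 at day 49 and 0.00199 at day 91. At day 91 the adjusted p was 0.178 with an estimated correlation, and 7 members were called (11 adjusted over the list alone). TAPBP was 0.96 ± 0.17 higher at day 7, 1.51 ± 0.17 at day 28 and 0.04 ± 0.17 at day 91, but the test of any difference among days missed the threshold (adjusted p = 0.0569). In a contrast chosen after seeing the data its effect was lower at day 91 than at day 28 (difference -1.47 ± 0.24, adjusted p = 0.0179). For the list that difference had a median of -0.41 and a camera adjusted p of 0.00141 (adjusted p = 0.524 with an estimated correlation), with TAPBP as the 1 member called.

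**Figure D3:**
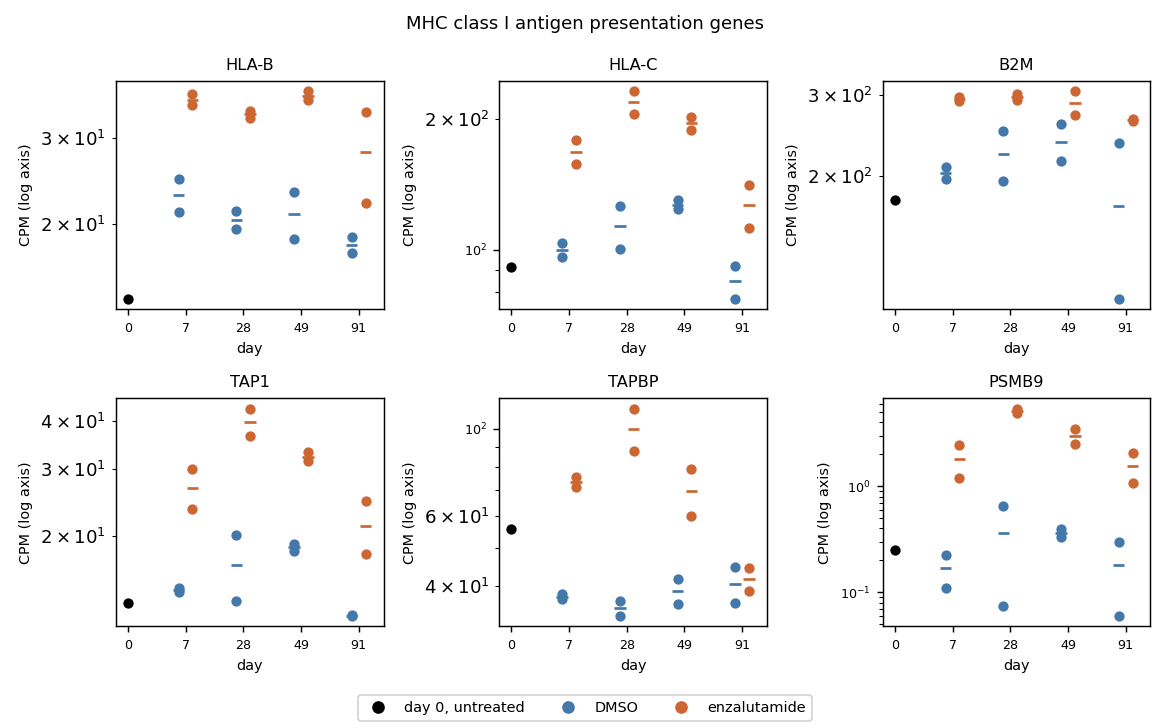
CPM on a log axis against day for 6 genes of MHC class I antigen presentation, with 1 point per library and a bar at each mean of 2 libraries. The mean of HLA-C in enzalutamide lies above that in DMSO on all 4 days, with log2 differences of 0.75, 0.95, 0.62 and 0.58.

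Of 32 interferon-stimulated genes, 16 rose and 6 fell (camera adjusted p = 0.0166, and adjusted p = 0.218 with an estimated correlation). IFIT1 rose by 3.04 ± 0.20, the transcription factor gene IRF1 by 1.65 ± 0.14 and the RNA sensor gene DDX58 by 0.99 ± 0.11. Of 14 immune ligands and checkpoints, 10 rose and 2 fell (adjusted p = 0.00633, adjusted p = 0.0527 with an estimated correlation, 0.0527 with the cell cycle score as a covariate and 0.137 among genes with a mean CPM of at least 5). ULBP2, a ligand of the NKG2D receptor, rose by 1.44 ± 0.11 and CD47, which inhibits phagocytosis, by 0.72 ± 0.08, while the death receptor gene TNFRSF10B fell by 0.64 ± 0.10. DDX58 (0.71, adjusted p = 0.212), CD47 (0.31, adjusted p = 0.478) and TNFRSF10B (-0.44, adjusted p = 0.513) were not called with the cell cycle score as a covariate. That score does not overlap between the treatments and standard errors rose with it, so a lost call does not show that cell division explains a change. Of 8 measured MHC class II genes 3 rose, and the list was not called by camera (adjusted p = 0.321), although it was without a filter on low counts (0.0401) and by fry, which tests the list alone (0.0012). HLA-DPA1 rose by 2.30 ± 0.19 (1.78 with the covariate, adjusted p = 0.0629), and HLA-DRA at day 49 was at least 9.47-fold higher than in DMSO, where both libraries were at 0 (limit of 3 counts over the group). For these lists the counts adjusted over the list alone were the same. NF-kB targets were not called as a list (2 rose, 2 fell of 8, adjusted p = 0.583).

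All 31 cell cycle genes were higher in enzalutamide (median 1.56, camera adjusted p = 1.9e-17, but adjusted p = 0.243 with an estimated correlation, since these genes vary together). CDC20 rose by 1.97 ± 0.15, TOP2A by 1.67 ± 0.15 and CCNB1 by 1.58 ± 0.14. TOP2A (0.49, adjusted p = 0.358) and CCNB1 (0.42, adjusted p = 0.304) were not called with the cell cycle score, which is made from these genes, as a covariate. Of 14 homologous recombination genes 13 rose, and 14 adjusted over the list alone (adjusted p = 8.92e-07, and adjusted p = 0.243 with an estimated correlation), among them RAD54L (1.66 ± 0.16) and EXO1 (1.62 ± 0.22). With the cell cycle score as a covariate the median of this list went from 1 to -0.27 (adjusted p = 0.384), EXO1 to -0.26 and RAD54L to 0.77 (adjusted p = 0.299). The mean log2 CPM of the cell cycle list was 3.78 to 4.75 in DMSO libraries, 5.19 to 6.77 in enzalutamide libraries and 6.16 in the day 0 library. Of 15 genes of the unfolded protein and integrated stress response, 8 fell and 1 rose (adjusted p = 0.00912, and adjusted p = 0.712 with an estimated correlation). The call was lost without day 28 (adjusted p = 0.133), without enzalutamide day 91 replicate 2 (0.0983) and with the cell cycle score as a covariate (0.778), where the list median was 0.12 against -0.36. TRIB3 fell by 1.71 ± 0.26 and ASNS by 1.13 ± 0.19 (-0.22 and 0.12 with the covariate, adjusted p = 0.923 and 0.931), and enzalutamide libraries spread from 6.15 to 8.33 in the mean of this list.

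**Figure D4:**
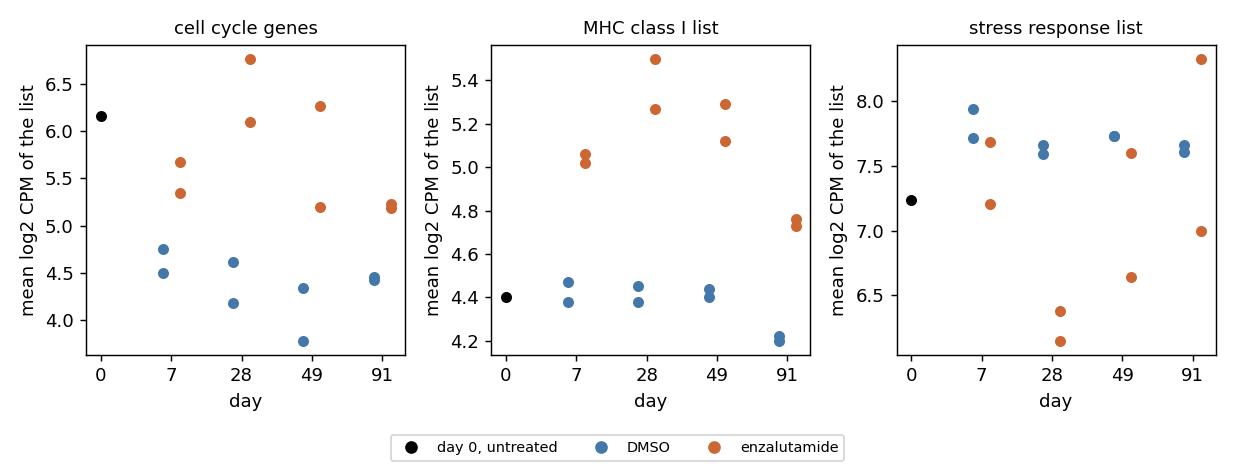
Mean log2 CPM of 3 gene lists against day, with 1 point per library. For cell cycle genes the day 0 library (6.16) lies above every DMSO library (at most 4.75), whereas for the MHC class I list it lies within the DMSO range (4.40).

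Lists of cell identity were not called by camera. Of 10 luminal markers 2 rose and 4 fell, or 5 adjusted over the list alone (adjusted p = 0.583), with SPDEF lower (-0.83 ± 0.07) and HOXB13 higher (0.62 ± 0.08). Of 11 neuroendocrine markers 3 rose and 2 fell (adjusted p = 0.753), and ENO2 rose by 0.55 ± 0.16. Basal markers (2 rose and 2 fell of 7, adjusted p = 0.771) included ITGB4 (1.46 ± 0.11), and mesenchymal transition genes (2 rose and 1 fell of 6, 3 and 1 adjusted over the list alone, adjusted p = 0.928) included VIM (-0.91 ± 0.09). Steroid synthesis and inactivation genes were split (3 rose and 3 fell of 18, adjusted p = 0.728), as were cholesterol and fatty acid synthesis genes (10 rose and 4 fell of 21, 11 and 4 adjusted over the list alone, adjusted p = 0.279, but 0.0496 without a filter and 0.0426 without enzalutamide day 49 replicate 2), among which ELOVL5 fell by 1.66 ± 0.09. Markers of other cell types did not move one way. Of 6 fibroblast markers COL1A1 alone was called (0.87 ± 0.14, list adjusted p = 0.728). Of 4 leukocyte markers PTPRC rose (2.30 ± 0.50) while CD4 (-1.62 ± 0.33) and CD68 (-0.48 ± 0.16) fell (list adjusted p = 0.753), at mean levels of at most 3.23 CPM in either treatment. When the cell cycle score was a covariate, PTPRC (0.61, adjusted p = 0.883), CD4 (-2.11, adjusted p = 0.33), CD68 (-0.14, adjusted p = 0.933) and COL1A1 (1.11, adjusted p = 0.146) were not called, nor were HOXB13 (0.52, adjusted p = 0.236), ENO2 (0.50, adjusted p = 0.668) and VIM (-0.81, adjusted p = 0.0904). CD4 and COL1A1 lay farther from 0 with the covariate, and the other genes of this group nearer. Since the score does not overlap between the treatments and standard errors rose, these lost calls do not show that cell division explains the changes. CD68 was also lost without a filter (0.063), without day 28 (0.0789) and without DMSO day 7 replicate 1 (0.0509), DMSO day 91 replicate 2 (0.0597), enzalutamide day 7 replicate 1 (0.0564), day 28 replicate 1 (0.0555) or day 91 replicate 2 (0.0558). Of 4 endothelial and red cell markers VWF alone was called (-1.96 ± 0.31, list adjusted p = 0.455).

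Across all 23137 genes, 10062 were called for the mean of 4 days, 5219 higher and 4843 lower, and 8711 of them had the same sign on 4 days. At least a 2-fold change was seen in 3075. Among the largest increases were PGR, the progesterone receptor gene (5.58 ± 0.39), the presynaptic gene UNC13C (5.6 ± 0.24), the phospholipase gene PLA2G2A (5.04 ± 0.41), the matrix gene TNC (4.68 ± 0.41), and PLPPR1, CDH18, SLITRK3, MATN2, CNTN5 and MYLK at 3.67 to 4.72. Among the largest decreases were RALYL (-5.78 ± 0.16), AFF3 (-5.49 ± 0.29), the sialyltransferase gene ST6GALNAC1 (-5.15 ± 0.12), S100P (-4.83 ± 0.32) and RND3 (-4.51 ± 0.20), followed by MYBPC1, PRSS1, KCNN2, BMPR1B, TENM1 and GRIN3A. With the cell cycle score of each library as a covariate, an alternative chosen after seeing the data, 582 genes were called, TNC (3.21, adjusted p = 0.076) and PRSS1 (-1.66, adjusted p = 0.502) not among them, and the median standard error of the 10062 genes went from 0.12 to 0.30.

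By day, 1229 genes were called at day 7 (793 higher, 436 lower), 5479 at day 28 (3072 and 2407), 3211 at day 49 (1859 and 1352) and 2930 at day 91 (1746 and 1184). PGR was already 5.68 ± 0.79 higher at day 7, and ZACN was 4.57 lower. Among protein-coding genes with a mean log2 CPM of at least 1, UGT2B15 had the largest called increase at days 28 (6.98 ± 0.45) and 49 (7.18 ± 0.45), and TNC at day 91 (6.42 ± 0.89). RALYL had the largest called decrease at day 91 (-7.36 ± 0.36). On all 4 days 739 genes were called, 507 always higher and 232 always lower. Each single-day count rests on 4 libraries and moved by more than 1.5 times without some of them. At day 7 it was 396 and 419 without DMSO replicates 1 and 2, and 474 and 404 without enzalutamide replicates 1 and 2. At day 28 it was 2776 without DMSO replicate 2 and 2260 without enzalutamide replicate 1. At day 49 it was 1807 and 1229 without DMSO replicates 1 and 2, and 1231 without enzalutamide replicate 1. At day 91 it was 1074 without DMSO replicate 2, and 1863 and 1731 without enzalutamide replicates 1 and 2. With only the groups compared the count was 3268 at day 7, 2026 at day 49 and 1432 at day 91, and without a filter it was 2364 at day 7. Log2 fold changes of different days, which share no libraries, correlated across genes at Pearson r = 0.461 (days 7 and 49) to 0.605 (days 28 and 49), at 0.722 to 0.887 among genes with a mean CPM of at least 5, and at 0.163 to 0.244 without a filter. Genes are not independent replicates, and if the days were sampled from the same cultures, a difference between cultures could recur on each day.

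**Figure D5:**
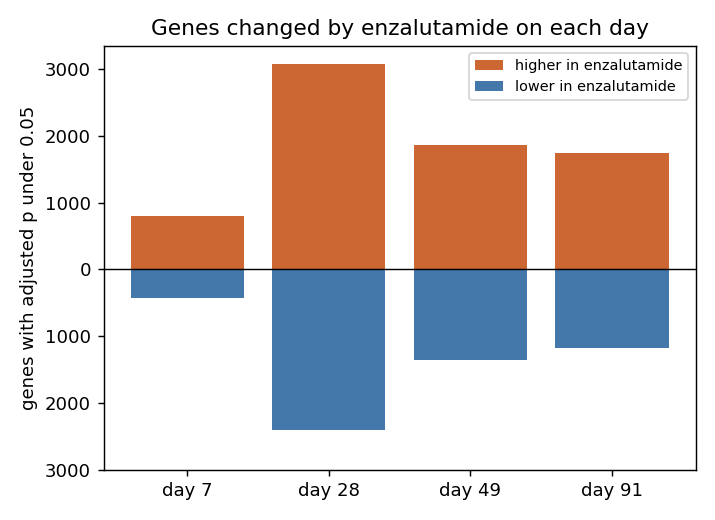
Number of genes with an adjusted p under 0.05 on each day, with genes higher in enzalutamide above 0 and lower ones below. Day 28 has 3072 higher and 2407 lower, and day 7 has 793 and 436.

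The time contrasts asked what changed between days 7 and 91. In DMSO, edgeR called 0 genes (smallest adjusted p = 0.119), with 1537 at an unadjusted p under 0.05 where 1157 would arise by chance, and limma voom called 0, DESeq2 28 and edgeR without a filter on low counts 168. Without single libraries edgeR called up to 5. In enzalutamide 77 genes were called, 29 higher and 48 lower at day 91, against 263 by DESeq2, 510 without a filter and 4 with only the groups compared. KLK2 rose by 2.96 ± 0.37 (adjusted p = 0.00197), so that at day 91 it was no longer called against DMSO (-0.75 ± 0.34, adjusted p = 0.159). Its call over time was lost without enzalutamide day 7 replicate 2 (adjusted p = 0.087). The cytokine gene TSLP (4.82 ± 0.73), the cation channel gene TRPM8 (2.54 ± 0.47), AADAT (2.21 ± 0.35) and PTGFR (1.94 ± 0.31) rose too. GULP1 (-3.63 ± 0.36), RALYL (-3.56 ± 0.42) and TFPI, an inhibitor of coagulation (-3.21 ± 0.25), fell. Without enzalutamide day 7 replicate 1 or 2 the adjusted p was 0.146 or 0.186 for TSLP, 0.217 or 0.31 for TRPM8, 0.19 or 0.171 for AADAT and 0.146 or 0.197 for PTGFR. TRPM8 was also lost without most DMSO libraries (0.05 to 0.0556) and, like PTGFR (0.0537), without enzalutamide day 91 replicate 2 (0.153). By voom TSLP (0.143), TRPM8 (0.106) and RALYL (0.106) were not called. With only the groups compared TSLP (0.259), TRPM8 (0.272), AADAT (0.259), PTGFR (0.0957) and RALYL (0.233) were not. The count was 18 and 10 without enzalutamide day 7 replicates 1 and 2, and 40 to 51 without DMSO day 7 replicate 1 or 2, day 49 replicate 1 or 2, or day 91 replicate 1 or 2. No member of the MHC class I list was called over time in enzalutamide, and 3 were called lower when adjusted over the list alone. Camera placed the list lower at day 91 (adjusted p = 8.49e-05, and adjusted p = 0.251 with an estimated correlation), but the difference of its enzalutamide effect between days 91 and 7 was not called (adjusted p = 0.593).

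The enzalutamide effect itself differed between days 91 and 7 in 10 genes, 9 of which had a mean log2 CPM of at least 1. SH3BGRL (difference 2.21 ± 0.22, adjusted p = 0.000867), HMGN5 (2.29 ± 0.38), DENND1B (1.81 ± 0.23), NLGN1 (1.72 ± 0.26) and LUZP2 (1.63 ± 0.24) had a higher fold change at day 91. TFPI (-3.12 ± 0.32, adjusted p = 0.000867), RALYL (-3.15 ± 0.49), GULP1 (-3.06 ± 0.47) and PRUNE2 (-1.72 ± 0.26) had a lower one. The calls of SH3BGRL and TFPI held without each library in turn, and those of the other 7 genes were each lost in at least 1 case, and with only the groups compared (adjusted p = 0.104 to 0.208). RALYL was also lost by voom (0.493). SH3BGRL (chromosome X, 81201943 to 81298547, plus strand) and HMGN5 (81113701 to 81201942, minus strand) are direct neighbours. KLK2 missed this threshold (2.73 ± 0.49, adjusted p = 0.0996). The count for days 91 and 7 was 2 to 6 without any 1 of the DMSO libraries or of the enzalutamide day 7 libraries, 31 and 18 without enzalutamide day 91 replicates 1 and 2, 66 by DESeq2, 271 without a filter and 3 with only the groups compared. A difference among the 4 days was found for 67 genes, against 531 by DESeq2, 1530 without a filter and 113 among genes with a mean CPM of at least 5. That count was 12 to 41 without any 1 of the libraries of DMSO day 7, DMSO day 28 or enzalutamide day 7, or without DMSO day 49 replicate 2, DMSO day 91 replicate 2 or enzalutamide day 28 replicate 1. It was 124 and 241 without enzalutamide day 49 replicates 1 and 2, and 155 without enzalutamide day 91 replicate 2.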

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

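The tests of the KLK2 pattern and its target list, of shared HLA reads, of the day 0 library and of scaling, and the cell cycle score as a covariate, were chosen only after the result was seen, as was the jackknife error of the list median under that covariate.

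The enzalutamide effect differed between days 91 and 7 in 10 genes and among the 4 days in 67 genes, by tests of the difference itself. Between days 91 and 7 the log2 differences were 2.29 for HMGN5, 2.21 for SH3BGRL, 1.81 for DENND1B, 1.72 for NLGN1, 1.63 for LUZP2, -3.15 for RALYL, -3.06 for GULP1, -3.12 for TFPI and -1.72 for PRUNE2. The calls of SH3BGRL and TFPI held without each library in turn, and those of the other 7 genes did not. Among the 4 days the adjusted p was 0.00369 for SH3BGRL, 0.00392 for TFPI, PTGFR and PRUNE2, 0.0142 for ST6GALNAC1, 0.0181 for DENND1B, 0.0194 for CNTN5, 0.0198 for NLGN1, 0.0209 for VIM, 0.0254 for GULP1, 0.0257 for KLK2 and LUZP2, 0.0417 for RALYL, 0.0419 for CCNB1 and 0.0438 for RND3.

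KLK2 under enzalutamide rose between days 7 and 91 while KLK3, TMPRSS2 and FKBP5 were still called lower than in DMSO at day 91. A constant share of reads taken over from its neighbour KLK3 is argued against. Under enzalutamide the log2 change between these days was 2.96 for KLK2 and 0.24 for KLK3, a difference of 2.72. KLK3 was more abundant (mean log2 CPM 10.15 against 7.1 for KLK2). The comparison therefore cannot exclude a changed share of KLK3 reads as the source of the KLK2 rise. A single library is also argued against as the source of its size, since the lowest log2 change with 1 library left out was 2.68, although the call itself was lost in that setting (adjusted p = 0.087). Among the 30 receptor activated genes KLK2, TRPM8 and KLK4 were called higher at day 91 (7 adjusted over the list alone), with a camera adjusted p of 7.94e-06 (adjusted p = 0.311 with an estimated correlation). The list also moved up in DMSO (2.61e-05, and adjusted p = 0.391 with an estimated correlation), and the difference of the enzalutamide effect between these days was called neither for the list (0.363) nor for KLK2. Between days 91 and 28, a contrast chosen after seeing the data, 5 members had a higher effect at day 91 and 1 a lower one (8 and 5 adjusted over the list alone). Camera did not call the list there (adjusted p = 0.0572, and adjusted p = 0.602 with an estimated correlation). For the 10 receptor repressed genes the enzalutamide effect was higher at day 91 than at day 7. The median difference was 0.95 (camera adjusted p = 0.00124, and adjusted p = 0.132 with an estimated correlation), with no member called over all genes. Over the same days that list moved down in DMSO (median -0.9, adjusted p = 0.00104, and adjusted p = 0.156 with an estimated correlation). In enzalutamide it was not called (0.869). A return of expression in part of the activated targets remains a hypothesis.

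The day 0 library, which entered no comparison, had a mean log2 CPM of cell cycle genes of 6.16, above every DMSO library. The higher level of these genes in enzalutamide than in DMSO does not come from a scaling factor common to all genes of a library, which would move other genes alike, since the list median exceeded that of all genes by 1.61 ± 0.25 (jackknife standard error over 16 libraries). A candidate explanation is the state of the DMSO cultures: the day 0 library lay 1.41 above the highest DMSO library, as a lower level of division in the DMSO cultures would give. It is 1 library, and a stimulation of division by enzalutamide stays open, as do differences in density or feeding, which the labels do not record.

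The rise of the MHC class I list does not come from reads shared among HLA genes alone, since 11 of 16 members outside the HLA genes were called higher. Whether the rise follows the difference in cell division cannot be told from these libraries. With the cell cycle score as a covariate the list median was 0.48 against 0.54 (0.44 to 0.57 without single libraries), and camera called the list (adjusted p = 0.000275). The median of the homologous recombination list went from 1 to -0.27. That of the cell cycle list went from 1.56 to 0.19, but the score is made from its genes. The margin is narrow: the median exceeded 0.5 of the one without the covariate by 0.21 ± 0.18 (jackknife standard error over 16 libraries), little more than 1 standard error. With the covariate 1 of 21 members was called: 8 of the 17 called without it moved nearer to 0, among them TAPBP (0.84 to 0.36), and the median standard error went from 0.10 to 0.27, while with an estimated correlation the list had an adjusted p of 0.0761. Since the scores of the treatments do not overlap (at most 4.75 in DMSO and at least 5.19 in enzalutamide), the covariate cannot separate cell division from treatment. An effect of enzalutamide on the pathway remains a hypothesis.

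For the number of genes changed in the mean of 4 days, a chance division of these libraries is argued against. Of 100 splits of the 16 libraries into 2 against 2 within each day, 1, the real one with 10062 genes, gave as many. The other splits had a median of 0 genes, but placing both treatments in 1 group widens its spread and lowers such counts. The highest other split gave 6019 and kept the real grouping on 3 of the 4 days. Where the 2 libraries of a group share a culture, the splits cover technical spread and not chance differences between cultures. Such differences are also missed where the days of a treatment share a culture.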

How the results depend on the processing

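The cell cycle score, alone or with an estimated correlation, the mean without day 28, the contrasts of day 28 with days 91 and 7, and for correlations all settings except the filter at a mean CPM of 5, were chosen after seeing the data. The count for the mean of 4 days stayed within 1.5 times of 10062 under DESeq2's size factors, DESeq2, voom, no filter, the additive model, an adjusted p under 0.01 and without day 28 (7230), and was 8867 to 10378 without single libraries. Both main lists kept their direction, and their call except that of MHC class I with the cell cycle score and an estimated correlation together (adjusted p = 0.0761, without single libraries 9.76e-07 to 5.56e-06 for MHC class I and 2.39e-20 to 1e-16 for receptor activated genes). Of 2603 values of named genes for the mean of 4 days, 2498 kept direction and call, 92 lost the call (49 of them with the covariate) and 13 changed sign. Of 546 values of lists, 504 kept both, 16 lost the call, 8 gained it and 18 changed sign. Besides the MHC class II and cholesterol lists, those that gained it did so with fry (NF-kB 0.0329, luminal 0.0312, leukocyte 0.0447, endothelial 0.0329). The cause was not tested unless stated.

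With a log2 fold change of at least 1 the counts were 3075 for the mean and 766, 2939, 1802 and 1637 by day, by construction. With an adjusted p under 0.01 they were 465, 2751, 1453 and 1128 by day, 18 for enzalutamide over time, 3 for days 91 against 7 and 9 among 4 days. Without a filter they were 2364 at day 7, 168 for DMSO over time, 510 for enzalutamide over time, 271 for days 91 against 7 and 1530 among 4 days. With a mean CPM of at least 5, which tests fewer genes, they were 6543 for the mean and 113 among 4 days. DESeq2 gave 28 for DMSO over time, 263 for enzalutamide over time, 66 for days 91 against 7 and 531 among 4 days. With only the groups compared they were 3268, 2026 and 1432 at days 7, 49 and 91, 4 for enzalutamide over time and 3 for days 91 against 7. With the cell cycle score 582 genes were called for the mean, where standard errors also rose.

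The replicate numbers did not pair the samples: same-numbered libraries of a day deviated with correlations of -0.002, -0.019, 0.023 and 0.034. With the replicate block 107 genes differed among 4 days, and with the replicate block within day 166 did and 18 changed in enzalutamide over time, while the other planned counts stayed within 1.5 times (10272 and 9657 for the mean). Of the added contrasts, days 28 against 7 gave 43 and 105, and days 91 against 28 gave 122 and 272. For enzalutamide over time the block within day left TSLP (0.165), TRPM8 (0.3), AADAT (0.152) and PTGFR (0.11) uncalled. For days 91 against 7 HMGN5 (0.0809 and 0.121) and RALYL (0.0559 and 0.0581) were uncalled with the replicate block and with that within day.

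Without single libraries the counts were 396 to 1600 at day 7, 2260 to 5907 at day 28, 1229 to 3613 at day 49, 1074 to 3365 at day 91, 0 to 5 for DMSO over time, 10 to 114 for enzalutamide over time, 2 to 31 for days 91 against 7 and 12 to 241 among 4 days. A lone library was then assumed to vary like the other groups.

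Correlations between days, in the order 7 and 28, 7 and 49, 7 and 91, 28 and 49, 28 and 91, 49 and 91, were 0.201, 0.163, 0.205, 0.244, 0.236 and 0.182 without a filter and 0.823, 0.814, 0.778, 0.887, 0.722 and 0.762 at a mean CPM of at least 5, so low-count genes set their size. The first 5 were 0.575, 0.508, 0.555, 0.65 and 0.577 with voom. Without single libraries they were 0.426 to 0.518, 0.38 to 0.461, 0.407 to 0.517, 0.492 to 0.622, 0.433 to 0.534 and 0.382 to 0.509. Their spread was taken as the SD over these left-out values.

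Values that changed sign were not called in the setting where they did, except the cholesterol list (adjusted p = 0.00152, lower with the cell cycle score). With that score log2 fold changes were -0.18 for TAP2, -0.09 for FANCI, -0.26 for EXO1, -0.12 for DST, -0.1 for FN1, 0.02 for ATF4 and 0.12 for ASNS, and adjusted p was 0.384 for homologous recombination, 0.761 for mesenchymal and 0.778 for steroid lists. With an estimated correlation as well it was 0.411 for homologous recombination, 0.777 for mesenchymal, 0.78 for steroid and 0.357 for cholesterol lists. Lists that turned without a filter had adjusted p of 0.812 (basal, mesenchymal, fibroblast) and 0.84 (leukocyte). NF-kB targets turned at a mean CPM of 5 (0.612), and the mesenchymal list with fry (0.277), DESeq2 (0.766) and without DMSO day 7 replicate 1 (0.887), DMSO day 91 replicate 1 (0.941) or enzalutamide day 49 replicate 1 (0.989), with a range of 0.76 to 0.989 over all single libraries. NLRC5 was 0.04 without day 28 and -0.2 to 0.02 without single libraries.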

Other observations

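The tests of a difference between days 91 and 28 and between days 28 and 7 were chosen only after seeing that day 28 had the most calls.

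The cell cycle, stress response and MHC class I lists were called by camera at day 7, at day 28 and at day 49, with different numbers of called members. At day 91 camera called the cell cycle list (adjusted p = 7.59e-07) and the MHC class I list (0.00199), and not the stress response list. Of 31 cell cycle genes 3 were called higher at day 7, 31 at day 28, 20 at day 49 and 7 at day 91, and 23, 31, 29 and 12 adjusted over the list alone. The list medians were 0.90, 2.27, 2.15 and 0.72. Of 15 stress response genes 9 were called lower at day 28 (median -1.31), among them TRIB3 (-3.29 ± 0.56), ASNS (-2.17 ± 0.39) and ATF4 (-1.68 ± 0.28), and 1 on each other day, with 11 at day 28 and 1 on each other day adjusted over the list alone. At day 91 HSPA5 (1.48 ± 0.43) and SDF2L1 (1.64 ± 0.36) were called higher, CREB3L4 lower (-1.07 ± 0.15), and 4 higher and 1 lower adjusted over the list alone. The list median was then 0.26, whereas camera gave the direction as lower (adjusted p = 0.82). The 2 enzalutamide libraries of day 91 disagreed in the mean log2 CPM of this list. Replicate 1 (8.33) lay above and replicate 2 (7) below every DMSO library (7.59 to 7.94). With an estimated correlation the adjusted p of these 2 lists was 0.185 to 0.6 (cell cycle) and 0.411 to 0.935 (stress response) over the 4 days. For the single genes, the test of a difference among days called CCNB1 (adjusted p = 0.0419) and not CDC20 (0.0567), TOP2A (0.104), TRIB3 (0.416), ASNS (0.473) or ATF4 (0.356).

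The enzalutamide effect was also compared between days 91 and 28 and between days 28 and 7. It differed in 101 genes between days 91 and 28 (54 higher and 47 lower at day 91). This count was 54 by voom, 518 by DESeq2, 1129 without a filter, 163 at a mean CPM of at least 5 and 7 at an adjusted p under 0.01. It stayed within 1.5 times without enzalutamide day 28 replicate 2 (113) or day 91 replicate 1 (68), and was 2 (without DMSO day 28 replicate 2) to 383 (without DMSO day 91 replicate 1) over all single libraries. Between days 28 and 7 it differed in 8 genes, 7 by voom, 189 by DESeq2, 697 without a filter, 34 at a mean CPM of at least 5 and 1 at an adjusted p under 0.01, and each left-out library moved that count by more than 1.5 times, from 0 (without DMSO day 7 replicate 1) to 102 (without enzalutamide day 49 replicate 1 or 2). The cell cycle list had a lower effect at day 91 than at day 28 (median difference -1.36, camera adjusted p = 6.04e-15, and adjusted p = 0.524 with an estimated correlation), with PLK1 (-2.75 ± 0.45), AURKA (-2.34 ± 0.40), CCNB1 (-2.01 ± 0.40) and CDC20 (-1.95 ± 0.40) called and 17 of 31 adjusted over the list alone. The stress response list had a higher one (1.45, adjusted p = 2.38e-07, and adjusted p = 0.524 with an estimated correlation), with 11 of 15 called only when adjusted over the list alone. Between days 28 and 7 the medians were 1.13 for the cell cycle list (adjusted p = 4.43e-17, and adjusted p = 0.351 with an estimated correlation), -1.10 for the stress response list (2.23e-05 and 0.422) and 0.36 for the MHC class I list (0.00439 and 0.351). No member of these was called over all genes, and 15 cell cycle genes higher and 5 stress response genes lower were called adjusted over the list alone.

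Of the NF-kB targets TNFAIP2 (1.47 ± 0.21) and RELB (1.11 ± 0.20) rose for the mean of 4 days, and NFKBIA (-0.29 ± 0.09) and CCL20 (-1.05 ± 0.33) fell, the last pair without a call when day 28 was left out. None of these was called with the cell cycle score as a covariate (TNFAIP2 0.31, adjusted p = 0.833, RELB 0.97, adjusted p = 0.452, NFKBIA -0.42, adjusted p = 0.438, CCL20 -0.16, adjusted p = 0.966). Among nuclear receptor genes, NR3C1, which encodes the glucocorticoid receptor, went from 0.216 to 5.25 CPM on average (2.95 ± 0.48) and NR3C2, which encodes the mineralocorticoid receptor, from 9.57 to 3.15 CPM (-1.61 ± 0.22). With that covariate neither was called (1.79, adjusted p = 0.478, and -0.87, adjusted p = 0.576). The score does not overlap between the treatments and standard errors rose with it, so none of these lost calls shows that cell division explains a change. NR3C1 was called higher at days 49 (5.04 ± 0.84) and 91 (6.38 ± 0.84) and not at days 7 (adjusted p = 0.483) and 28 (0.614). The difference of its effect was not called between days 91 and 7 (5.20 ± 1.25, adjusted p = 0.286) or among the 4 days (0.0569). It was called between days 91 and 28 (7.19 ± 1.35, adjusted p = 0.0383). For NR3C1, 5 of the 8 enzalutamide libraries lay above all DMSO libraries, and for NR3C2 all 8 lay below them.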
